A study of Homo sapiens with 8 samples.

How the data were processed

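The series holds 8 one-colour expression arrays of MCF7 cells, 2 for each of 4 groups: 5.6 or 30 mM glucose for 72 h, without or with 25 nM insulin. Per the labels, the cells grew in MEM with serum, RNA was purified on RNeasy columns, amplified with an Agilent kit that primes on poly(A) with oligo dT, and labelled with Cy3. Per the file headers, the arrays were read with Agilent Feature Extraction 11.5.1.1 and all lay on 1 slide. Per the file headers, the processed intensity of each spot had its background subtracted and was detrended across the array, with surrogate values for dim spots, and was not normalized between arrays. The deposited table holds log2 values for each gene name. Set against the scanner files, its columns equal log2 of the processed intensity less a single constant for each array, within 0.02 for at least 99.95% of 32308 genes with a single probe. The authors' own description of the processing is not given in the sources used here.

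The arrays carry 60901 spots that are not controls, for 58201 probes. Probe positions and gene names came from the scanner files (hg19), and current symbols were matched by accession for 31104 of 33080 probes with a RefSeq accession. No annotation of exons or untranslated regions was available, so only probe coordinates are given. The main values were log2 of the processed intensity minus the array's 75th percentile over all probes that are not controls, after averaging repeated spots and leaving out 44 probes with outlier marks. Probes well above background on at least 2 of 8 arrays were kept (28268), and each gene was represented by the probe with the highest mean, which gave 21992 genes, 14860 of them with a symbol. On single arrays 40.9% to 47.9% of probes were well above background, and the median standard error of a difference between 2 groups was 0.17 (log2).

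Group means were fitted with limma 3.58.1 in R 4.3.3, with the data.table package (1.17.8) for reading, and tested with moderated statistics (lmFit and eBayes, 4 residual degrees of freedom, prior 2.17), two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. The 8 comparisons were insulin at each glucose level, glucose at each insulin level, both together against the control, the interaction, and the 2 averaged effects. For the same comparisons 28 gene lists with 633 genes, 569 of them measured, were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Some genes are in several lists, so the calls are not independent. ASNS, SHMT2 and MTHFD2 are in the lists of ATF4 targets and of glutamine metabolism, and SLC7A11 is in those of ATF4 and NRF2 targets. SESN2 is in those of ATF4 and p53 targets, and AKR1B10 in those of NRF2 targets and polyol genes. The list of fibroblast and stromal markers had 4 measured genes, under the minimum of 5, so 27 lists were tested. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

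The comparisons, lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each comparison with the control, the 10 genes with the largest difference each way among those past the threshold, with no overlap between arrays and well above background on both arrays of a group (5 each way for the other comparisons). Where fewer passed, it took those and up to 3 each way with the smallest p. It added the 4 members with the smallest p of each called list, and 17 genes in every comparison: TXNIP, ARRDC4, IRS2, INSR, IGF1R, HMGCS1, LDLR, FASN, SCD, ESR1, PGR, GREB1, CCND1, MYC, MKI67, CDH1 and VIM. Genes outside the rule, namely the abundant RNAs with RNA28SN5, DDIT3 in the comparison of insulin at 30 mM, CHAC1 in that of glucose with insulin, and ATP1B2 in that of glucose and insulin together, were chosen after their values were seen.

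The alternatives fixed in this way were quantile normalization, normexp background subtraction (offset 50), the authors' table, no filter, a filter on all 8 arrays, the mean of a gene's probes, only the arrays compared, the set number as a replicate block, a trend in the prior variance, and leaving out each array in turn. Data were simulated with a spread that followed its trend with mean signal on the arrays and was equal in all groups. In these data 250 genes in all were changed at each of several sizes over 5 simulations. The test as used recovered 0%, 28.8%, 78% and 86% of genes changed by 0.5, 1, 2 and 3 (log2), and 28 of 510 calls were false. With the trend 8.8%, 52.8%, 85.2% and 89.2% were recovered, and 25 of 615 calls were false. A list shifted by 0.15, 0.3 or 0.6 was called in 5 of 5 simulations with the preset correlation, and in 0, 4 and 5 with an estimated one. A list with a mean near 0.15 can thus miss the threshold with an estimated correlation although its genes are independent. At each size 0 of 130 unshifted lists were called with the preset correlation. The simulated genes were drawn independently, so these counts do not measure false calls where genes are correlated or groups differ in spread.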

Results

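Gene expression was measured in MCF7 cells, an estrogen receptor positive human breast cancer line, after 72 h in medium with 5.6 or 30 mM glucose, each without or with 25 nM insulin. The labels describe these conditions as models of normal and high blood sugar and of high insulin, and the title places the series in the relation between diabetes and breast cancer. Each of the 4 groups had 2 one-colour arrays, 8 in all, and cells in 5.6 mM glucose without insulin served as the control. On each array 40.9% to 47.9% of the 58201 probes were well above background, the 75th percentile of the processed intensity ran from 141 to 189, and 0 spots were saturated. The number of arrays limits the precision: the median standard error of a difference between 2 groups was 0.17 on the log2 scale. Differences are given as log2 difference ± standard error from limma, with p-values adjusted over 21992 genes, and levels as log2 signal relative to the array's 75th percentile with the SD (n = 2). The labels number the arrays of a group as sets and do not say whether the sets are separate cultures. The limma p-values of single genes therefore measure only the spread between samples. Those of camera with the preset correlation compare the members of a list with the other genes. However small, they do not measure how well a list repeats between arrays or cultures.

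Several features of the arrays moved with the groups. Abundant RNAs, chosen after their values were seen, were higher in all 3 treated groups than in the control. The medians of 15 ribosomal, 7SK and mitochondrial transcripts were 0.63 with insulin, 0.83 with 30 mM glucose and 1.23 with both (SE 0.26 each). The 28S ribosomal RNA gene RNA28SN5 stood at 8.74 and 8.66 on the control arrays and between 9.42 and 10.1 on the other 6. The medians of 176 small nucleolar and nuclear RNAs, which lack a poly(A) tail and were also examined after their values were seen, differed from the control by 0.31 with insulin, 0.21 with 30 mM glucose and 0.27 with both. Signal also shifted with gene span on single arrays. Relative to the mean of the control arrays, the median of the 25% of genes with the longest span less that of the 25% with the shortest was -0.01 and -0.19 on arrays 1 and 2 with insulin at 5.6 mM, -0.11 and -0.03 with 30 mM glucose, and -0.11 and 0.14 with both. Array 2 of the group with 30 mM glucose and insulin, the only array scanned on its own, lay apart from the rest, at -27.7 on a principal component with 40.4% of the variance that placed the other 7 arrays between -0.03 and 7.90. The replicate SD over 10797 brighter genes was 0.24 in that group, against 0.08 in the control, 0.14 with insulin at 5.6 mM and 0.11 with 30 mM glucose alone. All arrays with 5.6 mM glucose lay in slide row 1 and all arrays with 30 mM in slide row 2, so glucose level and slide row cannot be told apart. All arrays without insulin lay in slide columns 1 and 2 and all arrays with insulin in columns 3 and 4, so insulin and slide column cannot be told apart either.

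**Figure D1:**
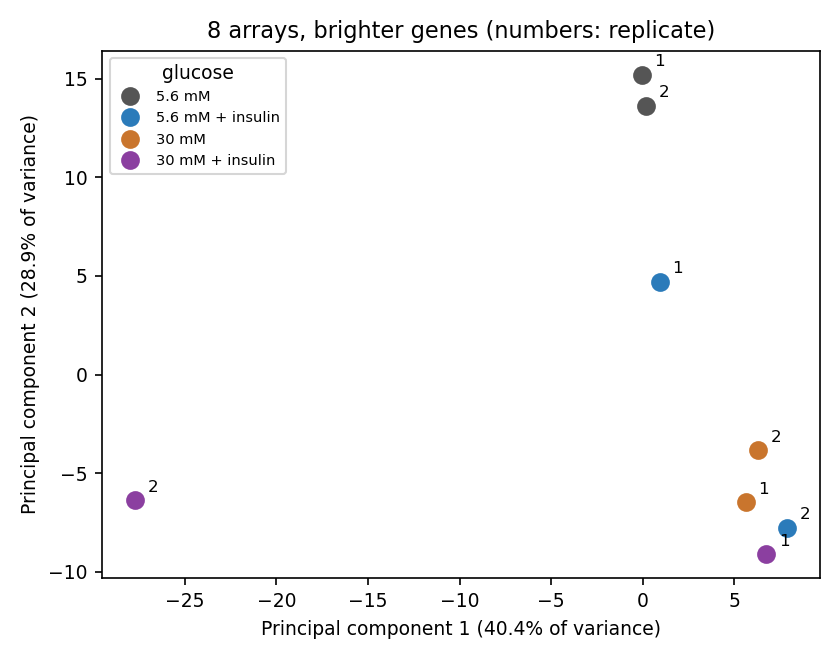
Scores of the 8 arrays on principal component 1 (40.4% of the variance, horizontal axis) and 2 (28.9%, vertical axis), computed over 10797 brighter genes, coloured by group and numbered by replicate. Array 2 of the group with 30 mM glucose and insulin sits at -27.7 on the horizontal axis, and the other 7 sit between -0.03 and 7.90.

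The comparison of insulin with no insulin at 5.6 mM glucose asked how high insulin alone acted on the cells. Genes of the amino acid response, the targets of the stress transcription factor ATF4, rose together, with 26 of 28 measured members higher and a mean difference of 0.63 (camera, adjusted p = 6.14e-22). The adjusted p = 0.13 with an estimated correlation between genes. DDIT3, which encodes the stress-induced factor CHOP (probe on chromosome 12, 57911200 to 57911526, hg19), went from -0.61 ± 0.04 in the control to 2.21 ± 0.43 with insulin, a difference of 2.82 ± 0.21. CHAC1, an enzyme that degrades glutathione (chromosome 15, 41248631 to 41248690), differed by 1.57 ± 0.14. DDIT4, an inhibitor of mTORC1 (chromosome 10, 74035363 to 74035422), differed by 1.47 ± 0.14, and ATF3, a stress-induced transcription factor, by 1.23 ± 0.13 with 3 of its 4 probes in that direction and a range of 0.16 to 1.27 over the alternatives. Of the 28 members, 19 passed when adjusted over the list alone. Adjusted over all genes 0 passed in limma, 20 were higher at an unadjusted p under 0.05, and 5 passed with a trend in the prior variance, an alternative planned with the design.

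The NRF2 oxidative stress genes also rose with insulin at 5.6 mM glucose, with 17 of 24 higher and a mean of 0.33 (adjusted p = 6.62e-05; adjusted p = 0.49 with an estimated correlation). HMOX1, the heme-degrading enzyme heme oxygenase 1 (chromosome 22, 35790122 to 35790181), differed by 1.77 ± 0.12. The aldo-keto reductases AKR1B10 and AKR1C1 differed by 1.55 ± 0.32 and 1.32 ± 0.17, and AKR1B10, which was dim, by 0.36 with normexp background. Of these 24 genes, 5 passed adjusted over the list alone, 0 passed over all genes in limma, 7 had an unadjusted p under 0.05 and 2 passed with the trend. In the other direction, markers of basal and myoepithelial cells fell, with 12 of 12 measured members lower and a mean of -0.38 (adjusted p = 9.77e-05; adjusted p = 0.19 with an estimated correlation). CAV1 and CAV2, which form caveolae, differed by -1.21 ± 0.22 and -0.53 ± 0.11, and ITGB4, an integrin of hemidesmosomes, by -0.39 ± 0.10. Adjusted over the list alone 3 of the 12 passed, and 0 passed over all genes in limma, with 3 at an unadjusted p under 0.05 and 1 with the trend. TXNIP, a glucose-responsive inhibitor of glucose uptake (chromosome 1, 145442447 to 145442506), went from 6.32 ± 0.06 to 5.06 ± 0.18, a difference of -1.26 ± 0.12. The keratin gene KRT23 differed by -1.13 ± 0.13, with a range of -1.16 to -0.30 over the alternatives.

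Smaller shifts with insulin at 5.6 mM glucose were called for 7 further lists. Cholesterol synthesis and uptake genes rose by a mean of 0.12 (17 of 23 higher; adjusted p = 0.48 with an estimated correlation), although the authors' table gave a mean of -0.01 for them. The unfolded protein response rose by 0.11 (12 of 20; adjusted p = 0.49 with an estimated correlation), led by HERPUD1, a factor of protein disposal at the endoplasmic reticulum, at 0.67 ± 0.12. Replication-dependent histones rose by 0.11 (18 of 20; adjusted p = 0.63 with an estimated correlation), a mean that was 0.23 without insulin array 1 and -0.000491 without insulin array 2. Most histone transcripts of this list lack a poly(A) tail, and beside their rise the small RNAs without one stood at 0.31 and the shift with gene span at -0.01 and -0.19 on insulin arrays 1 and 2. Glutamine and one-carbon metabolism was called upward with a mean of 0.11 and a median of -0.01, opposite in sign, with GPT2, an alanine aminotransferase, at 0.72 ± 0.12 (adjusted p = 0.49 with an estimated correlation). Genes of G1/S and DNA replication fell by a mean of 0.12 (28 of 34 lower), those of G2/M and mitosis fell by 0.14 (27 of 32), and adjusted p = 0.62 with an estimated correlation for both. Estrogen-repressed genes fell by 0.16 (15 of 18 lower; adjusted p = 0.49 with an estimated correlation). Adjusted over each list alone, 2 estrogen-repressed genes and 1 gene each of the cholesterol, unfolded protein and glutamine lists passed. Among genes named in advance, the insulin receptor INSR differed by -0.55 ± 0.18, with -0.32 without insulin array 2 and -0.79 without array 1. Its adaptor IRS2 differed by -0.36 ± 0.21, with -0.23 without control array 2 and -0.50 without control array 1. The lipid genes HMGCS1, LDLR, FASN and SCD differed by -0.10 to 0.06, and the estrogen receptor ESR1 by 0.15 ± 0.16 (0.10 without insulin array 2, 0.20 without array 1). None of these genes passed. The 15 abundant RNAs were all higher on these insulin arrays, with the median of 0.63 given above.

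With limma 0 genes passed for insulin at 5.6 mM glucose, 1557 had an unadjusted p under 0.05 where chance gives 1100, and 34 passed with the trend (27 higher, 7 lower). DDIT3 and HMOX1 had the smallest adjusted p, 0.061 each. Over 16 alternatives the adjusted p of DDIT3 ran from 7.9e-15 to 0.52, past the threshold in 6, and that of HMOX1 from 6.6e-12 to 0.52, past it in 7. For TXNIP (adjusted p = 0.16) the range was 2.3e-07 to 0.86, past it in 4. Leaving out control array 2 took the number of called lists from 10 to 4. The ATF4, NRF2 and basal lists kept their calls without each of the 4 arrays, and so did the cholesterol list. The other 6 each lost theirs without at least 1 array, with adjusted p between 0.063 and 0.48 (control array 2 for all 6, insulin array 1 or 2 as well).

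**Figure D2:**
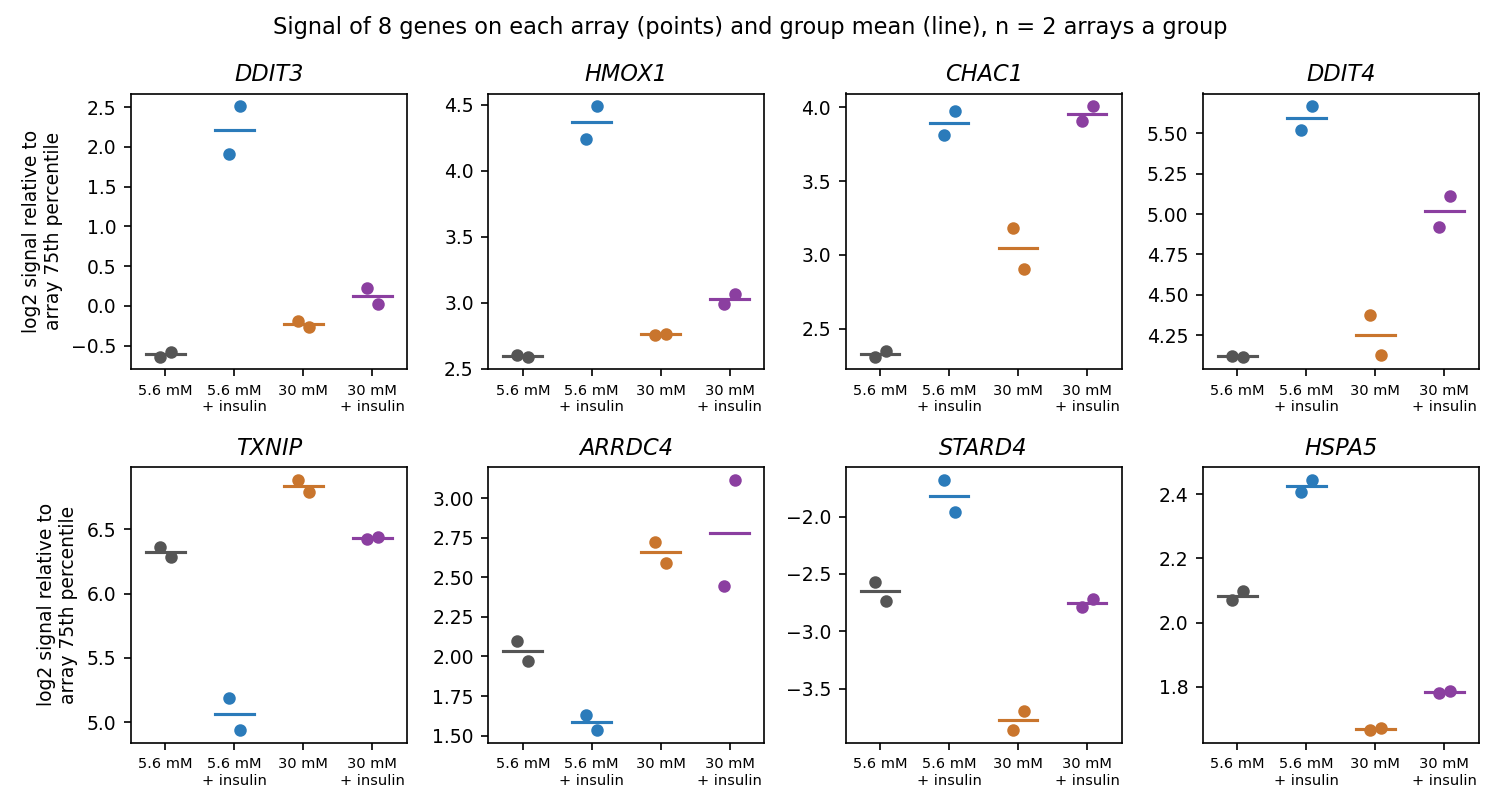
Log2 signal relative to the array's 75th percentile (vertical axis) of 8 genes on each array (points) in the 4 groups (horizontal axis), with the group mean as a line (n = 2). DDIT3 stood at 2.21 with insulin at 5.6 mM and at 0.12 with insulin at 30 mM glucose, and TXNIP was lowest, at 5.06, with insulin at 5.6 mM.

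The comparison of 30 with 5.6 mM glucose in the absence of insulin asked how high glucose alone acted on the cells. Genes of cholesterol synthesis and uptake fell at 30 mM, with 17 of 23 lower and a mean of -0.18 (adjusted p = 0.0151; adjusted p = 0.54 with an estimated correlation). STARD4, a carrier of cholesterol between membranes (chromosome 5, 110834688 to 110834747), differed by -1.13 ± 0.14, and by -0.28 with normexp background. INSIG1, the sterol-sensing anchor of SREBP processing, differed by -0.47 ± 0.13 and HMGCS1, which makes the mevalonate precursor HMG-CoA, by -0.46 ± 0.13. Genes of the unfolded protein response fell as well, with 18 of 20 lower and a mean of -0.17 (adjusted p = 0.0151; adjusted p = 0.54 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum (chromosome 9, 127997149 to 127997208), differed by -0.42 ± 0.10, from 2.08 ± 0.02 to 1.67 ± 0.00, and the disulfide isomerase PDIA6 by -0.42 ± 0.12. Replication-dependent histones rose, with 17 of 20 higher and a mean of 0.22 (adjusted p = 0.000204; adjusted p = 0.67 with an estimated correlation), among them H3C2 at 0.48 ± 0.16 and H4C8 at 0.45 ± 0.14. Beside them the small RNAs without a poly(A) tail stood at 0.21 and the shift with gene span at -0.11 and -0.03 on glucose arrays 1 and 2.

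With 30 mM glucose alone, p53 targets and apoptosis genes were also higher by a mean of 0.13 (21 of 30 higher) and ATF4 targets by 0.14 (23 of 28 higher). Each had adjusted p = 0.54 with an estimated correlation. GDF15, a stress-induced secreted factor, differed by 0.59 ± 0.13, CHAC1 by 0.72 ± 0.14, and SESN2, a leucine sensor that restrains mTORC1, by 0.44 ± 0.15. Genes of G1/S and DNA replication fell by a mean of 0.12 (28 of 34 lower; adjusted p = 0.77 with an estimated correlation). Genes of G2/M and mitosis fell by 0.13 (25 of 32 lower; adjusted p = 0.8 with an estimated correlation), among them the topoisomerase TOP2A at -0.49 ± 0.16 and HMMR, a spindle-associated protein, at -0.52 ± 0.14. MKI67, a further proliferation marker named in advance, differed the other way, by 0.55 ± 0.21 (0.35 with normexp background). TXNIP and ARRDC4, transcripts that follow cellular glucose through the factor MondoA, differed by 0.51 ± 0.12 and 0.62 ± 0.22. The desaturase SCD differed by -0.47 ± 0.12 and the mesenchymal filament gene VIM by -0.50 ± 0.13, and none of the genes named in advance passed. CHD9, a chromatin remodeler, had the smallest p among the named genes that were higher, at 0.82 ± 0.10 (0.51 in the authors' table). Of the abundant RNAs, 14 of 15 were higher at 30 mM glucose, with a median of 0.83.

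Adjusted over each list alone, 1 cholesterol gene and 1 ATF4 target passed for glucose without insulin, and 0 members of the other 5 lists. With limma 0 genes passed over all genes, 2200 had an unadjusted p under 0.05 where chance gives 1100, and 6 passed with the trend (2 higher, 4 lower). The balance of directions differed between settings, with 43 of 60 higher with normexp background, 13 of 32 in the authors' table, and 137 of 271 with the trend and array 2 of 30 mM glucose with insulin left out. The adjusted p of STARD4 was 0.28, and ran from 0.048 to 1.0 over 16 alternatives. The number of called lists went from 7 to 4 without control array 2, to 3 without glucose array 1 and to 4 without glucose array 2. Histones kept their call without each array, with a mean of 0.15 without glucose array 1. Cholesterol genes lost it without control array 2 (adjusted p = 0.059) or glucose array 2 (0.11), the unfolded protein response without glucose array 2 (0.11), ATF4 targets without glucose array 1 (0.23, mean 0.08) and p53 targets without glucose array 1 (0.07). G1/S genes lost it without each of the 4 arrays (0.067 to 0.25) and G2/M genes without either control array or glucose array 1 (0.079 to 0.35).

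The comparison of 30 mM glucose and insulin together with the control asked how the combined condition acted. ATF4 targets rose, with 27 of 28 higher and a mean of 0.50 (adjusted p = 1.14e-13; adjusted p = 0.25 with an estimated correlation). CHAC1 differed by 1.63 ± 0.14 and DDIT4 by 0.90 ± 0.14. ATF3 differed by 0.88 ± 0.13 with 3 of its 4 probes in that direction, and the mean of its probes gave 0.18. Of the 28 members 16 passed adjusted over the list alone, 0 passed over all genes in limma, 16 had an unadjusted p under 0.05 and 5 passed with the trend. p53 targets and apoptosis genes rose, with 23 of 30 higher and a mean of 0.20 (adjusted p = 0.00324; adjusted p = 0.25 with an estimated correlation), among them GDF15 at 0.90 ± 0.13 and PMAIP1, which encodes the cell death protein NOXA, at 0.73 ± 0.17. Basal and myoepithelial markers fell, with 10 of 12 lower and a mean of -0.37 (adjusted p = 0.0196; adjusted p = 0.4 with an estimated correlation), and CAV1 and CAV2 differed by -0.98 ± 0.22 and -0.84 ± 0.11. Adjusted over each list alone, 3 p53 targets and 2 basal markers passed.

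Glutamine and one-carbon metabolism rose with glucose and insulin together, with 13 of 20 higher and a mean of 0.18 (adjusted p = 0.00813; adjusted p = 0.4 with an estimated correlation). GPT2 differed by 1.09 ± 0.12 and the asparagine synthetase ASNS, which is also in the ATF4 list, by 0.48 ± 0.13. NRF2 targets rose by a mean of 0.17 (20 of 24 higher, adjusted p = 0.71 with an estimated correlation). The cystine transporter SLC7A11, which is also in the ATF4 list, stood at 1.20 ± 0.27 and HMOX1 at 0.43 ± 0.12. Over 14 alternatives the NRF2 list kept its call in 9, with a mean down to 0.06. Histones rose by 0.15 (16 of 20 higher; adjusted p = 0.78 with an estimated correlation), and by 0.08 without array 1 of the combined group, beside small RNAs at 0.27 and a shift with gene span of -0.11 and 0.14 on its arrays 1 and 2. Epithelial genes rose by 0.13 (17 of 23 higher, adjusted p = 0.62 with an estimated correlation), with the mucin MUC1 at 0.60 ± 0.11. Over 14 alternatives the epithelial list kept its call in 6, with a mean down to 0.05. RDH12, a retinol dehydrogenase, differed by 1.37 ± 0.16 and KRT23 by -1.25 ± 0.13 (-0.46 in the authors' table). Of the genes named in advance, MKI67 differed by 0.74 ± 0.21 (0.42 in the authors' table), ARRDC4 by 0.74 ± 0.22 (0.41 without array 2 and 1.08 without array 1 of the combined group), VIM by -0.61 ± 0.13 and TXNIP by 0.11 ± 0.12 (0.07 without control array 2). MYC and the epithelial cadherin CDH1 differed by 0.15 ± 0.23 and 0.17 ± 0.26, by -0.21 and -0.24 without array 2 of the combined group, and by 0.51 and 0.57 without its array 1. Of the abundant RNAs, 14 of 15 were higher with glucose and insulin together, with a median of 1.23.

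Only 3 genes passed in limma for glucose and insulin together, all lower and all near the floor of the arrays. HOXA2, a homeobox gene (chromosome 7, 27140350 to 27140409), was at least 1.06-fold lower (adjusted p = 0.036) and was not well above background on either treated array. The homeobox gene PAX4 was lower (adjusted p = 0.036), well above background on the control arrays only, and its fold could not be bounded. The sodium pump subunit ATP1B2, named after its values were seen, passed as well (adjusted p = 0.036) but was well above background on 0 arrays of this comparison, so no fold is given. The number passing went to 0 without control array 1, control array 2 or array 2 of the combined group, and to 5 without its array 1. Over all genes 2917 had an unadjusted p under 0.05 where chance gives 1100. With the trend 66 passed, 42 higher and 24 lower, and none of these 3 did (adjusted p 0.12 to 0.21). Over 14 alternatives the adjusted p of HOXA2 ran from 0.0056 to 0.88 and that of PAX4 from 0.0036 to 1.0. Over 15 alternatives the adjusted p of CHAC1 (0.067) ran from 1.4e-09 to 0.49. The called lists went from 7 to 4 without array 2 of the combined group, and only the ATF4 list kept its call without each array. The others lost theirs without control array 1 or 2 or array 1 or 2 of the combined group, with adjusted p from 0.057 to 0.29.

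The comparison of insulin with no insulin at 30 mM glucose asked whether insulin acted under high glucose. ATF4 targets rose here too, with 25 of 28 higher and a mean of 0.36 (adjusted p = 3.21e-11; adjusted p = 0.42 with an estimated correlation). CHAC1 differed by 0.91 ± 0.14, the lipoprotein receptor gene VLDLR by 0.82 ± 0.19 (0.54 without array 2 of the insulin group, 1.11 without array 1) and DDIT4 by 0.76 ± 0.14. DDIT3, which had the largest difference at 5.6 mM, went from -0.23 ± 0.05 to 0.12 ± 0.14. For ATF3 the chosen probe gave 0.62 ± 0.13, only 1 of 4 probes had that sign, and the mean of its probes gave -0.06. Adjusted over the list alone 4 ATF4 targets passed, 0 passed over all genes in limma or with the trend, and 12 had an unadjusted p under 0.05.

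With insulin at 30 mM glucose, cholesterol genes were higher by a mean of 0.15 (20 of 23 higher, adjusted p = 0.62 with an estimated correlation). STARD4 differed by 1.02 ± 0.14, and by 0.30 with normexp background. Glutamine and one-carbon genes rose by 0.13 (15 of 20, adjusted p = 0.62 with an estimated correlation), with GPT2 at 0.64 ± 0.12 and the mitochondrial folate enzyme MTHFD2 at 0.61 ± 0.23. NRF2 targets rose by 0.15 (19 of 24, adjusted p = 0.67 with an estimated correlation), with SLC7A11 at 0.83 ± 0.27. MTHFD2 and SLC7A11 are also in the ATF4 list. Polyol, hexosamine and osmotic response genes rose by 0.23 (15 of 16; adjusted p = 0.67 with an estimated correlation), with AKR1B10 at 0.78 ± 0.32 (0.18 with normexp background, 0.32 without array 2 and 1.24 without array 1 at 30 mM glucose alone). Ribosome biogenesis and MYC targets rose by 0.12 (23 of 28; adjusted p = 0.62 with an estimated correlation), with NOLC1, a nucleolar phosphoprotein, at 0.32 ± 0.16. Fatty acid and triglyceride synthesis rose by 0.10 (17 of 22, adjusted p = 0.62 with an estimated correlation). G1/S genes rose by 0.08 (25 of 34, adjusted p = 0.7 with an estimated correlation). Over 14 alternatives the fatty acid list kept its call in 1 and the G1/S list in 2, with means down to 0.035 and 0.010. With quantile normalization, and with no filter, the ATF4 list alone was called in this comparison. Without array 2 of the insulin group the means were 0.10 for polyol genes, 0.04 for fatty acid genes, 0.01 for G1/S genes, 0.07 for ribosome biogenesis and 0.08 for glutamine genes. There MTHFD2 stood at 0.26, SLC7A11 at 0.51 and NOLC1 at 0.10, against 0.97, 1.15 and 0.55 without array 1 of that group. Without its array 1 the means were 0.36, 0.17 and 0.14 for the polyol, fatty acid and G1/S lists. NRF2 targets stood at 0.23 without array 1 at 30 mM glucose alone and at 0.06 without its array 2, and polyol genes at 0.15 without the latter. Adjusted over each list alone, 1 cholesterol gene and 1 glutamine gene passed. TXNIP differed by -0.41 ± 0.12, INSR by -0.07 ± 0.18 and IRS2 by -0.31 ± 0.21. Without array 1 of the insulin group INSR stood at 0.05 and IRS2 at -0.03, and without its array 2 at -0.19 and -0.60. None of the genes named in advance passed.

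In limma 1 gene passed for insulin at 30 mM glucose. ATP1B2 was lower (adjusted p = 0.035) but well above background only on the 2 arrays without insulin, so its fold could not be bounded. It lost its call without each of the 4 arrays (adjusted p 0.064 to 0.26) and with the trend (0.69), over a range of 0.0041 to 1.0 in 14 alternatives. Over all genes 1256 had an unadjusted p under 0.05 where chance gives 1100, and 0 passed with the trend. Leaving out array 1 of the insulin group gave 3 genes. The called lists went from 8 to 1 without array 2 at 30 mM glucose alone and to 4 without array 2 of the insulin group. Only the ATF4 list kept its call without each array. The other 7 lost theirs without 1 or more of the 4 arrays, with adjusted p from 0.055 to 0.75.

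The comparison of 30 with 5.6 mM glucose in the presence of insulin asked how glucose acted on insulin-treated cells. Genes of the unfolded protein response fell, with 17 of 20 lower and a mean of -0.20 (adjusted p = 0.000909; adjusted p = 0.55 with an estimated correlation). HSPA5 differed by -0.64 ± 0.10, from 2.43 ± 0.03 to 1.78 ± 0.00, and MANF, a protective factor secreted under stress, by -0.40 ± 0.11. Cholesterol genes fell, with 19 of 23 lower and a mean of -0.15 (adjusted p = 0.0122; adjusted p = 0.55 with an estimated correlation), with STARD4 at -0.94 ± 0.14 (-0.22 with normexp background) and INSIG1 at -0.42 ± 0.13. DDIT3 differed by -2.09 ± 0.21 and HMOX1 by -1.34 ± 0.12, whereas CHAC1 stood at 3.90 ± 0.12 without and 3.96 ± 0.07 with high glucose. IL24, a cytokine of the IL-10 family, differed by -1.43 ± 0.16, and by -0.62 in the authors' table. TXNIP and ARRDC4 differed by 1.37 ± 0.12 and 1.20 ± 0.22.

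With limma 0 genes passed for glucose with insulin, 1680 had an unadjusted p under 0.05 where chance gives 1100, and 4 passed with the trend, namely TXNIP upward and DDIT3, HMOX1 and IL24 downward. Of those passing, 4 of 16 were higher with normexp background and 26 of 36 in the authors' table. The adjusted p of TXNIP was 0.12 and ran from 1.2e-07 to 0.47 over 15 alternatives. That of DDIT3 was 0.13 and ran from 1.9e-11 to 0.46, each past the threshold in 5. The smallest adjusted p, 0.087, belonged to the steroid sulfatase gene STS, which was at least 1.71-fold higher and not well above background at 5.6 mM. Adjusted over the list alone 1 gene of each called list passed. Without array 1 of insulin at 30 mM 3 genes passed over all genes. The called lists went from 2 to 1 without array 2 of insulin at 5.6 mM and to 4 without its array 1 or without array 1 of insulin at 30 mM. Without the last, both the cholesterol and the unfolded protein list lost their calls (adjusted p = 0.15 each), and the cholesterol list did so without array 2 of insulin at 5.6 mM as well (0.068).

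**Figure D3:**
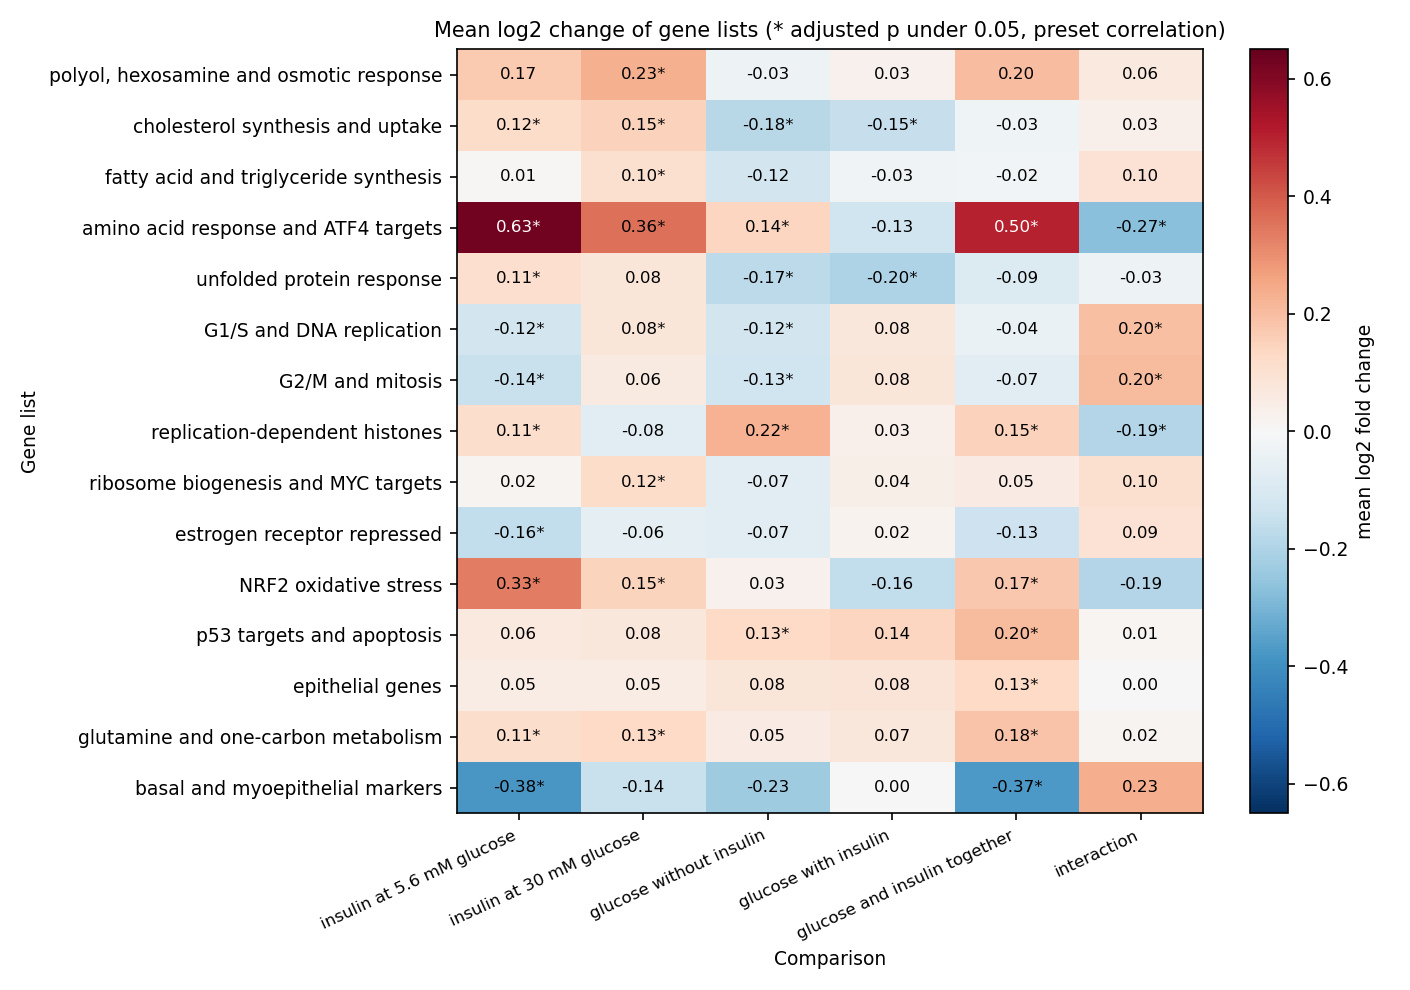
Mean log2 difference (colour and printed value) of 15 gene lists (vertical axis) in 6 comparisons (horizontal axis), with a star where camera with a preset correlation gave an adjusted p under 0.05. ATF4 targets stood at 0.63 with insulin at 5.6 mM, 0.36 with insulin at 30 mM and 0.50 with glucose and insulin together.

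The interaction asked whether the effect of insulin differed between 30 and 5.6 mM glucose, as the difference of the 2 insulin effects. ATF4 targets had a smaller insulin effect at 30 mM, with 19 of 28 interactions below 0 and a mean of -0.27 (adjusted p = 0.00179; adjusted p = 0.92 with an estimated correlation). DDIT3 had an interaction of -2.47 ± 0.29 and HMOX1 of -1.50 ± 0.17, and adjusted over the list alone 1 ATF4 target passed. SESN2, DDIT4 and ATF3 followed at -0.73 ± 0.21, -0.71 ± 0.20 and -0.61 ± 0.18, and that of ATF3 was 0.69 in the authors' table. Histones were lower, by a mean of -0.19 (16 of 20 below 0), which was -0.08 without array 2 and -0.30 without array 1 of insulin at 5.6 mM, the arrays with a shift with gene span of -0.19 and -0.01. Genes of G1/S and DNA replication and of G2/M and mitosis were higher, by 0.20 each (28 of 34 and 27 of 32 above 0), and adjusted p = 0.92 with an estimated correlation for all 3 lists. The cytokinesis gene ANLN had an interaction of 0.64 ± 0.26 (0.41 without array 2 and 0.88 without array 1 of insulin at 30 mM), and TXNIP and ARRDC4 had 0.85 ± 0.18 and 0.58 ± 0.31 (0.24 for ARRDC4 without array 2 and 0.91 without array 1 of insulin at 30 mM).

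In limma 1 gene passed for the interaction, the antisense RNA gene GPR84-AS1 (adjusted p = 0.043). It was well above background only on 2 arrays, so its fitted interaction of 4.10 sets no bound. It did not pass with the trend (adjusted p = 0.75, over a range of 0.004 to 0.99 in 17 alternatives), and lost its call without each of the 8 arrays (0.072 to 0.55). Over all genes 1068 had an unadjusted p under 0.05 where chance gives 1100. With the trend 2 genes passed, DDIT3 and HMOX1, both below 0, whereas 1 of 5 lay above 0 with normexp background and 26 of 34 in the authors' table. Of those 34, at least 25 averaged different probes on different arrays, 24 of them with a change over 2 (log2). The adjusted p of DDIT3 (0.27) ran from 3.9e-08 to 0.77 over 18 alternatives, and that of HMOX1 (0.25) from 1.4e-05 to 0.77. Without array 1 at 30 mM glucose 0 of the 4 lists were called, with adjusted p of 0.072 for ATF4 targets, 0.068 for G1/S, 0.11 for G2/M and 0.28 for histones (mean -0.11). Without array 2 of insulin at 30 mM the G2/M and histone lists were lost (0.092 each), at means of 0.11 and -0.12. Without array 1 of insulin at 30 mM the ATF4 list (0.11) and the histone list (0.05, mean -0.26) lost their calls. Without array 2 of insulin at 5.6 mM the G2/M and histone lists lost theirs (0.069 and 0.26) and 2 lists were called. The number of genes passing was 3 without array 1 of insulin at 30 mM, and 0 or 1 without each other array.

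Averaged over both glucose levels, ATF4 targets were higher with insulin, with 26 of 28 higher and a mean of 0.49 (camera, adjusted p = 2.54e-24). The adjusted p was 0.11 with an estimated correlation. CHAC1 differed by 1.24 ± 0.10, DDIT4 by 1.12 ± 0.10 and DDIT3 by 1.58 ± 0.15. Of the 28, 21 passed adjusted over the list alone, 0 over all genes in limma, 21 had an unadjusted p under 0.05 and 10 passed with the trend. NRF2 targets rose by a mean of 0.24 (17 of 24 higher; adjusted p = 0.32 with an estimated correlation) with HMOX1 at 1.02 ± 0.09. Cholesterol genes rose by 0.14 (20 of 23; adjusted p = 0.2 with an estimated correlation), with STARD4 at 0.93 ± 0.10 (0.27 with normexp background). Glutamine and one-carbon genes rose by 0.12 (12 of 20) and the unfolded protein response by 0.10 (14 of 20), each with adjusted p = 0.32 with an estimated correlation. Ribosome biogenesis rose by 0.07 (22 of 28; adjusted p = 0.47 with an estimated correlation) and oxidative phosphorylation by 0.06 (22 of 30; adjusted p = 0.55 with an estimated correlation). Polyol and osmotic genes rose by 0.20 (10 of 16; adjusted p = 0.61 with an estimated correlation) and interferon response genes by 0.12 (17 of 29; adjusted p = 0.65 with an estimated correlation). The interferon mean was 0.02 without array 2 of insulin at 5.6 mM or array 1 of insulin at 30 mM, 0.22 without array 1 of insulin at 5.6 mM and 0.23 without array 2 of insulin at 30 mM. Those of oxidative phosphorylation and ribosome biogenesis were 0.03 and 0.04 without array 2 of insulin at 5.6 and at 30 mM. Basal and myoepithelial markers fell, with 11 of 12 lower and a mean of -0.26 (adjusted p = 0.000542; adjusted p = 0.2 with an estimated correlation). Adjusted over each list alone, 5 NRF2 targets and 3 basal markers passed. TXNIP differed by -0.83 ± 0.09, KRT23 by -0.87 ± 0.09 (-0.47 with normexp background) and KCNJ8, a potassium channel gene, by -0.62 ± 0.07. With limma 0 genes passed, 1737 had an unadjusted p under 0.05 where chance gives 1100, and 45 passed with the trend (36 higher, 9 lower). Without array 1 of insulin at 30 mM 3 genes passed. The ATF4, NRF2, cholesterol and basal lists kept their calls without each of the 8 arrays. The other 6 lost theirs without 1 to 4 of them, with adjusted p from 0.058 to 0.72.

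Averaged over both insulin conditions, unfolded protein response genes were lower at 30 mM glucose, with 17 of 20 lower and a mean of -0.18 (camera, adjusted p = 0.000257). The adjusted p was 0.29 with an estimated correlation. HSPA5 differed by -0.53 ± 0.07 and PDIA6 by -0.39 ± 0.08. Cholesterol genes fell, with 20 of 23 lower and a mean of -0.16 (adjusted p = 0.00182; adjusted p = 0.29 with an estimated correlation), with STARD4 at -1.03 ± 0.10 (-0.25 with normexp background) and INSIG1 at -0.45 ± 0.09. Adjusted over each list alone, 4 and 2 genes passed. TXNIP and ARRDC4 differed by 0.94 ± 0.09 and 0.91 ± 0.16, IL24 by -1.10 ± 0.11 (-0.60 in the authors' table) and CHD9 by 0.59 ± 0.07. p53 targets rose by a mean of 0.13 (24 of 30 higher, adjusted p = 0.29 with an estimated correlation) and histones by 0.13 (16 of 20, adjusted p = 0.87 with an estimated correlation). Over 18 alternatives the p53 list kept its call in 16, with a mean down to 0.04. Interferon response genes fell by 0.18 (23 of 29 lower; adjusted p = 1.0 with an estimated correlation), with IFI27, an interferon-induced mitochondrial protein, at -0.95 ± 0.27 (-0.52 with normexp background). The interferon mean was -0.08 without array 2 and -0.29 without array 1 of insulin at either glucose level, and the histone mean 0.07 without array 1 of insulin at 5.6 mM. In limma PAX4 alone passed and was lower (adjusted p = 0.016). It was well above background on 2 arrays only, so no fold is given. It missed the threshold with the trend (0.17, over a range of 0.0023 to 1.0 in 17 alternatives) and without each array except those of the combined group (0.09 to 0.33). Without array 1 of the combined group 8 genes passed. Over all genes 2589 had an unadjusted p under 0.05 where chance gives 1100, and 41 passed with the trend (20 higher, 21 lower). Of those passing, 61 of 108 were higher with normexp background and 24 of 34 in the authors' table. There at least 25 of the 34 averaged different probes on different arrays. The called lists went from 5 to 3 without array 1 at 30 mM glucose. The unfolded protein, cholesterol and p53 lists kept their calls without each array, and histones lost theirs without at least 1. Interferon genes lost theirs without either control array, either array of 30 mM glucose alone, or array 2 of insulin at either glucose level. Over 18 alternatives the histone list kept its call in 14 and the interferon list in 7.

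Fold changes were also compared between effects across 21992 genes, which are not independent replicates. The insulin effects at 5.6 and 30 mM, which share no arrays, correlated at -0.003 (Spearman 0.0285), and over 10797 brighter genes at 0.106. The glucose effects without and with insulin correlated at 0.095 (Spearman 0.14), and over brighter genes at 0.198. The averaged insulin and glucose effects correlated at 0.254, and at 0.282 without array 2 of the combined group. Data simulated without effects gave 0.0867 with each group's own spread, a simulation added after the values were seen, and -0.00517 with a spread pooled over the groups, which were not equally spread. The 3 effects measured against the same control arrays correlated at 0.59 for insulin with glucose, 0.515 for insulin with both and 0.575 for glucose with both. Sharing those arrays alone gave 0.361, 0.29 and 0.304 in data simulated with each group's own spread, and 0.497 to 0.5 with the pooled one. The covariances were 0.0717, 0.0713 and 0.0844 against 0.0257, 0.026 and 0.0262 with each group's own spread, and 0.0495, 0.0495 and 0.0497 with the pooled one, which is wider than that of the control arrays. All 3 effects rest on the same 2 control arrays, so the excess was not assigned to the control or to the treated groups.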

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

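The tests of ATF4 targets in this part were chosen after the result was seen, and the interaction itself was planned. The difference between arrays with and without insulin was not the same at the 2 glucose levels for 4 lists, by camera with a preset correlation. The interaction of ATF4 targets was -0.27, of G1/S and DNA replication genes 0.20, of G2/M and mitosis genes 0.20 and of histones -0.19, each with adjusted p = 0.92 with an estimated correlation. Without array 1 at 30 mM glucose 0 of the 4 were called, and the histone mean was -0.08 without array 2 of insulin at 5.6 mM. The antisense RNA GPR84-AS1 had an interaction of 4.10 (adjusted p = 0.043) at a signal near the floor, with an adjusted p of 0.75 with the trend, over a range of 0.004 to 0.99 in 17 alternatives, and lost its call without each of the 8 arrays (0.072 to 0.55).

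ATF4 targets were higher with insulin at 5.6 mM glucose by a mean of 0.63, and by 0.36 at 30 mM. Array brightness is argued against, since after quantile normalization the mean at 5.6 mM was still 0.63 (SE 0.0252), and so is a single array, since the largest adjusted p without each of the 4 arrays was 2e-12. A candidate explanation is that insulin-treated cultures used up the glucose in the 5.6 mM medium. The mean interaction of TXNIP and ARRDC4, whose transcripts follow glucose, was 0.71 in the direction this needs. The adjusted p was 0.75 for each with the trend. The explanation also needs no fall with insulin at 30 mM, where TXNIP differed by -0.41. ARRDC4 differed there by 0.12, but by -0.21 without array 2 of insulin at 30 mM, so the mean interaction rests partly on that array. The explanation stays undecided. A direct effect of insulin, which the design names, also stays open, was not tested and cannot be told apart from slide column, and the list was called with insulin at 30 mM as well.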

How the results depend on the processing

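The alternatives were planned except for 3 chosen after seeing the data: the percentile over detected probes, leaving array 2 of 30 mM glucose with insulin out of the spread, and leaving it out with a trend in the prior variance. No result past its threshold passed it in the other direction. The means of 2 called lists changed sign as the call was lost, both with insulin at 5.6 mM: cholesterol genes to -0.01 with the values of the authors, and histones to -0.000491 without insulin array 2. Of the values of named genes under alternatives, 6941 stayed on their side of the threshold, 314 passed it newly and 54 no longer passed. Differences that had not passed changed sign 148 times. Of those of called lists, 654 kept the call and 287 lost it. Of the counts, 145 stayed within 1.5 times and 128 moved, and of the correlations 28 stayed and 8 moved. Most probes were near the floor on these arrays, with 40.9% to 47.9% well above background. The offset of normexp background shrinks differences of dim genes by construction. Where an array is left out, the lone array of its group is assumed to vary like the others. Unless stated, the cause was not tested.

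Counts follow the order insulin at 5.6 mM, glucose without insulin, both together, insulin at 30 mM, glucose with insulin, interaction, averaged insulin and averaged glucose. The number of genes was 0, 0, 3, 1, 0, 1, 0 and 1 as reported. With a trend in the prior variance it was 34, 6, 66, 0, 4, 2, 45 and 41, and with array 2 of 30 mM glucose with insulin left out as well 152, 271, 174, 6, 14, 6, 127 and 293. With normexp background it was 87, 60, 238, 3, 16, 5, 83 and 108, and with the values of the authors it was 32, 32, 75, 39, 36, 34, 48 and 34. Quantile normalization gave 2, 1, 1, 2 and 2 for the first 5 comparisons. Genes well above background on all 8 arrays gave 10 and 1 for the first pair, 0 for insulin at 30 mM and the interaction, 3 for glucose with insulin, and 10 and 7 for the averages; the genes called as reported in the comparisons that went to 0 were not among those tested. The mean of a gene's probes gave 4 for insulin at 5.6 mM, 5 for both together and 2 for averaged insulin. With no filter, and with the set number as a replicate block, both together, insulin at 30 mM, the interaction and averaged glucose gave 0. The labels do not say that sets of different groups are paired. The deviations of arrays with the same number correlated at -0.0763 to 0.0113 over all genes and at -0.337 to 0.216 over brighter ones. With only the arrays compared, both together and insulin at 30 mM gave 0.

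The number of lists was 10, 7, 7, 8, 2, 4, 10 and 5 as reported. It was 0 in all 8 comparisons with an estimated correlation, and 2, 1, 1, 2, 0, 0, 3 and 2 with fry. In simulated independent genes a list shifted by 0.15 was called in 0 of 5 simulations with an estimated correlation. For lists with means of about that size, the lost call does not show that their genes were correlated. Quantile normalization gave 2 lists for both together and 1 for insulin at 30 mM. Normexp background gave 17 for insulin at 5.6 mM, 3 for insulin at 30 mM and 6 for glucose with insulin. The authors' table gave 4 for both together, 3 for insulin at 30 mM and 3 for averaged glucose. With no filter both together gave 2, insulin at 30 mM 1, glucose with insulin 5, averaged insulin 4 and averaged glucose 3. Well above background on all 8 arrays, and the percentile over detected probes, each gave 5 for insulin at 30 mM. The trend gave 5 for glucose with insulin and 7 for the interaction, and 6 for glucose with insulin with the array left out as well.

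Leaving out each array gave 0 to 5 genes for both together, 0 to 8 for averaged glucose, and 0 to 3 for insulin at 30 mM, glucose with insulin, the interaction and averaged insulin. Lists ran from 4 to 11 for insulin at 5.6 mM, 3 to 5 for glucose without insulin, 4 to 7 for both together, 1 to 9 for insulin at 30 mM, 1 to 4 for glucose with insulin, 0 to 5 for the interaction and 3 to 5 for averaged glucose. The correlation of the insulin effects (-0.003) was 0.041 with normexp, 0.0491 with the authors' table and 0.0799 with genes well above background on all 8 arrays. That of the glucose effects (0.095) was 0.142 with normexp, 0.0195 with no filter and 0.21 with all 8 arrays. With normexp insulin and both together correlated at 0.617, and glucose and both together at 0.664.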

Other observations

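The tests of abundant RNAs in this part were chosen after the result was seen, and those of other splits and of array 2 of 30 mM glucose with insulin before. Lists for several pathways tied to glucose and insulin were not called in limma's camera test in any comparison with the control. Targets of the glucose sensors MondoA and ChREBP differed by a mean of -0.22 with insulin at 5.6 mM (adjusted p = 0.0659), 0.04 with glucose and 0.04 with both, and by 0.26 for glucose with insulin (adjusted p = 0.0712). Adjusted over the list alone 3 of the 13 measured passed with insulin at 5.6 mM. Glycolysis genes differed by 0.06, 0.04 and 0.06 in the 3 comparisons with the control, in that order, and the pentose phosphate pathway by -0.03, -0.10 and -0.06. FOXO targets and insulin feedback genes differed by -0.17 (adjusted p = 0.114), -0.07 and -0.06. Oxidative phosphorylation differed by 0.06, 0.00 and 0.07, and estrogen-induced genes by -0.04, -0.09 and 0.01. Fatty acid synthesis differed by 0.01, -0.12 and -0.02, and ribosome biogenesis by 0.02, -0.07 and 0.05.

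Hypoxia genes differed by 0.06, -0.03 and 0.10, NF-kappaB and cytokine genes by 0.03, 0.05 and 0.02, and interferon response genes by 0.12, -0.19 and -0.06. Mesenchymal and invasion genes differed by -0.03, -0.21 and -0.25 (14 of 30 measured), and immediate early and heat shock genes by 0.03, -0.02 and -0.03. Markers of leukocytes and erythroid cells, with 10 of 18 measured, differed by -0.02, -0.05 and -0.05, and fibroblast markers, with 4 of 13 measured and no test, by -0.26, -0.22 and -0.26. Over all 8 comparisons the mean, the median and the test differed in sign for 37 of 163 uncalled pairs of list and comparison, and for 1 of 53 called ones, glutamine metabolism with insulin at 5.6 mM.

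Ribosomal, 7SK and mitochondrial RNAs were higher than in the control in all 3 treated groups. Without scaling to the 75th percentile the median differences were 0.61 with 30 mM glucose and 0.89 with both (SE 0.21 each), which argues against scaling as the whole cause there. With insulin at 5.6 mM, the group of the control's own slide row, the difference was 0.43 (SE 0.21) without scaling and 0.63 (SE 0.26) with it. Both clear the limit of 2 SE set for these tests only narrowly. With 2 arrays a group this decides neither scaling in that group nor slide row as the cause for the 15 as a set. For the 11 mitochondrial ones the difference was 0.80 (SE 0.18), and 0.60 (SE 0.19) without scaling, with all 11 higher. For the 4 ribosomal and 7SK RNAs it was 0.69 (SE 0.27), and 0.49 (SE 0.17) without scaling. The mitochondrial values argue against slide row, which this group shares with the control, as the cause of their difference here. A candidate explanation for the ribosomal and 7SK RNAs is that more RNA without a poly(A) tail was labelled. The medians of 176 small nucleolar and nuclear RNAs, 0.31, 0.21 and 0.27, all lay at percentile 100 of 10000 random lists, as this needs. The genes of those lists were matched for mean signal and drawn independently. Any class of RNAs that shifts together can reach such a percentile, so the result does not single out labelling. The 11 mitochondrial transcripts of the 15 had medians of 0.80, 0.68 and 1.14, and the explanation was not tested for them. A biological rise with glucose and insulin, the treatments of the design, stays open and was not tested.

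Array 2 of 30 mM glucose with insulin stood apart from its replicate, with a replicate SD of 0.241 in its group. Array brightness is argued against, since after quantile normalization the SD was 0.232 (highest other group 0.141). Gene span is also argued against, since after a smooth trend on span was removed the SD was 0.223 (highest other group 0.128). The separate scan of this array cannot be told apart from a difference between the cultures, as no other array was scanned alone, and no biological explanation was tested because its replicate had the same treatment.

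Every split of the 8 arrays into 4 and 4 was fitted as 2 groups, 35 in all, so the counts differ from those of the fit to 4 groups. Chance could not be excluded for the 4 counts above 0, and for the other 2, which were 0, the comparison with other splits decides nothing. For averaged insulin the real split called 0 genes and the highest other 2, 11 and 97 with the trend, and 9 and 10 lists. As many were called by 35, 2 and 4 of the 35 splits, the real one included. For averaged glucose the real split called 1 gene and the highest other 2, 0 and 97 with the trend, and 5 and 10 lists, and as many were called by 4, 35 and 12 splits. The split with 97 genes set both control arrays, array 1 of insulin at 5.6 mM and array 2 of both together against the rest, and points to a structure of the samples, whose source was not tested. The same arrays had the 4 highest shifts with gene span, -0.01 to 0.14 relative to the control mean, against -0.19 to -0.03 on the rest.

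The authors' table averaged, for genes with several probes, the probes well above background on each array. The rule gives a value only where at least 1 probe was well above background, and 99.5% of these 56297 values lay within 0.02 (log2). Averaging all probes gave 70.9% of 87664 values within 0.02, a larger set. How the remaining values were averaged was not worked out. Of 10958 such gene names, 1461 averaged different probes on different arrays. Of the genes called from that table, 16 of 32 for insulin at 5.6 mM, 15 of 32 for glucose without insulin, 39 of 75 for both together and 35 of 39 for insulin at 30 mM were of this kind. So were 25 of 36 for glucose with insulin, 25 of 34 for the interaction, 31 of 48 for averaged insulin and 25 of 34 for averaged glucose.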
